A study of Mus musculus with 4 samples.

How the data were processed

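The deposited count matrices held raw UMI counts per gene and barcode, made with Cell Ranger 5.0.0 per the file headers. The submitters' notes name Cell Ranger 5.0.0, Seurat 4.2.0 and the mm10 build. How the deposited barcodes were chosen is not given. The protocol text names reagents of different chemistry versions. Each pool was deposited as 2 entries, and their gene counts were equal in all of 30180890 nonzero entries for COL1 and STIFF and 28827102 for MATR and SOFT. Only the entry titled as gene expression held the 3 antibody rows, so each pool was read once. The files listed 32285 genes. Of these, 26335 symbols were in the reference annotation, and 38 shared by more than 1 identifier were kept separate.

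Settings, comparisons, gene lists and most alternatives were fixed before the data were examined. Barcodes with at least 1000 UMIs, at least 500 genes and at most 15% mitochondrial UMIs were kept, which was 90.1% and 90.6% of those deposited. Hashtags 1 and 2 of each pool were called with HTODemux of Seurat 5.3.0 in R 4.3.3 at a positive quantile of 0.99, which set cutoffs of 138 and 1358 counts in the COL1 and STIFF pool and 217 and 1161 in the MATR and SOFT pool. Barcodes positive for both tags (305 and 277) or for neither (5249 and 3394) were left out. By the share of barcodes with both tags, 8.38% and 6.59% of the singlets would be doublets within 1 tag. Scrublet marked 0 cells in either pool, so it did not work as a filter. As alternatives added after seeing the data, the 297 and 282 cells with the highest scrublet scores were left out, tags were called by the relative rule (larger tag at least 2 times the smaller after division by its background, both at least 4 times background called a doublet), unnamed clusters were left out, and tags were exchanged in the MATR and SOFT pool.

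Python 3.11.15 with scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9 was used. Singlets of both pools were clustered together without integration (log-normalised counts, 2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 0.5). Other barcodes were assigned to these clusters. A cluster took the class of the marker list with at least 3 members at 20 CPM or more and at least 2-fold above the median of the other clusters, and the list with the highest mean log2 ratio led. A cluster stayed unnamed where a further such list reached 0.5 of the leading list's mean, a ratio set after seeing the data, except that fibroblast and pericyte lists were not set against each other, or where its median depth was far below that of its pool. Classes with at least 100 cells in both conditions were compared, and where SOFT had fewer, the relative tag rule was used.

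For each comparison raw counts were summed over the cells of a condition and divided by their total, and the ratio has an exact 95% interval from the conditional binomial distribution. Shares of cells have exact Clopper-Pearson 95% intervals. Both cover counting error only, and cells of 1 culture varied by more. When the cells of a culture were split at random into equal groups, the interval excluded 1 for a median of 12.2% of genes in COL1, 13.3% in STIFF, 12.7% in MATR and 12.6% in SOFT, over 20 splits each. No paired analysis was possible with 1 culture per condition. Log2 ratios used a pseudocount of 10 CPM. Trimmed mean of M-values scaling would subtract 0.07 from them in COL1 over MATR and 0.05 in STIFF over SOFT. In COL1 over STIFF this is -0.01 and in MATR over SOFT -0.03. A count of 0 was read as allowing up to 3 counts.

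Genes were named by a rule. Among genes with at least 200 UMIs over both conditions and at least 50 CPM in 1 of them, the 12 with the highest and the 12 with the lowest log2 ratio over all singlets were taken, and 6 and 6 within each of the basal-like, HR-positive and HR-negative classes. Mitochondrial, ribosomal protein, haemoglobin and sex-linked marker genes and unnamed gene models were left out, and keratins and AP-1 subunits were given regardless of rank. A few chosen genes are left out of the text. The figure genes and a few named genes outside the rule were chosen after their values were seen. Of 24 pathway lists and 12 marker lists, members of at least 5 CPM in 1 condition counted as measured, and for pathway lists the members with the largest and smallest ratios serve as examples. A list's median was placed among 10000 random lists drawn from 20 expression bins. The lists described in the text were chosen after their values were seen. The level of a gene within a class was set beside its lowest level among the other classes of at least 50 cells in the same condition.

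Simulated counts from the sums of each comparison tested the procedure, without variation between cells or co-regulation within lists. Intervals covered the true ratio for 95.2% to 95.8% of genes. A 1.5-fold change was recovered for 98.5% to 100% of changed genes over all singlets and for 72.1% to 92.6% in the HR-negative class, and a 4-fold change for 100% of them. Of unchanged lists, 2.5% to 6% fell outside the random range, and all raised ones were found. Real lists may differ. The alternatives were other scalings, thinning of cells to 3000 UMIs, equal weights for cells, basal-like or luminal-like cells alone, other tag rules, a stricter cell filter of 3000 UMIs, 1500 genes and 10% mitochondrial UMIs, a pseudocount of 1 CPM, other clusterings, whole pools with tags ignored, and exchanged tags. Hashtag3, named for no condition, was not compared.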

Results

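Organoids grown from mammary fat pads of virgin mice, 8 to 9 weeks old, were cultured under 4 conditions and profiled by single-cell RNA sequencing. The conditions were Matrigel (MATR), a soft matrix (SOFT), a collagen matrix (COL1) and a stiff matrix (STIFF). Cells of 2 conditions at a time were marked with hashtag antibodies, which bind the cell surface and carry a readable tag, and loaded together on 1 channel of a droplet chip. COL1 and STIFF shared 1 channel, and MATR and SOFT shared the other. Each condition was 1 culture, so there were no biological replicates, no test of a difference was possible, and intervals cover counting error only. The COL1 and STIFF pool held 10615 barcodes with 133608252 unique molecule counts (UMIs), and the MATR and SOFT pool held 8767 barcodes with 131036333 UMIs.

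The cell filter kept 9568 barcodes of the COL1 and STIFF pool (median 10087.5 UMIs) and 7945 of the MATR and SOFT pool (median 12626 UMIs). Hashtags assigned 1563 cells to COL1, 2451 to STIFF, 2333 to MATR and 1941 to SOFT, with 23466134, 52611678, 43831075 and 37224614 summed UMIs. The labels do not say which tag belonged to which culture. The pairing was read from the names of the deposited matrices, and exchanging it would turn every COL1 over STIFF value around in the COL1 and STIFF pool and every MATR over SOFT value in the other. No tag was called on 54.9% of kept barcodes in the COL1 and STIFF pool and on 42.7% in the MATR and SOFT pool. This share depended on the class assigned to each barcode. It was 79.5% (77.6 to 81.3) and 71.2% (69.2 to 73.2) of hormone receptor-negative luminal-like barcodes in the pools, and 29.9% (28.1 to 31.8) and 30.2% (28.7 to 31.8) of receptor-positive ones. The relative tag rule, which sets each tag against its own background and was added after seeing the data, assigned 1780 cells to COL1, 5381 to STIFF, 2963 to MATR and 4173 to SOFT.

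Clustering gave 5 classes with enough cells to compare, named from markers fixed in advance. The basal-like class was cluster 0, led by Acta2, Tagln and Krt5. Hormone receptor-positive (HR-positive) luminal-like cells formed clusters 1, 2 and 4, and receptor-negative (HR-negative) luminal-like cells formed cluster 5, led by Saa1, Ltf and Csn3. Cluster 3 was fibroblast-like, with Col1a1 and Col3a1. It also carried 4 pericyte markers, at a mean log2 ratio of 2.61 against 5.10 for fibroblast markers, so fibroblasts and pericytes were not separated. Cluster 7 was immune-like, with the macrophage genes Lyz2 and C1qa. Cluster 10, 24 cells, was endothelial-like. Clusters 6, 8 and 9 stayed unnamed. Cluster 6, led by the macrophage genes Apoe, Lyz2, Tyrobp and C1qa, had a median of 1466.5 UMIs. Cluster 8 had markers of both luminal classes, 26295 median UMIs and the highest median doublet score, 0.126, so doublets stay open. Cluster 9 carried HR-negative and basal markers and cell cycle genes. The threshold that left 8 and 9 unnamed was set after seeing the data. Together the unnamed clusters held 19.8% (17.8 to 21.8) of COL1 cells, 24% (22.3 to 25.7) of STIFF, 14.4% (13.0 to 15.9) of MATR and 14.7% (13.1 to 16.3) of SOFT cells. For cluster 6 these shares were 5.18%, 0.245%, 0.214% and 0.309%. They were 8.06%, 18.7%, 12.1% and 7.11% for cluster 8, and 6.53%, 5.02%, 2.14% and 7.26% for cluster 9.

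The basal-like share was 14.7% (13.0 to 16.6) in COL1, 7.87% (6.84 to 9.01) in STIFF, 7.72% (6.66 to 8.87) in MATR and 3.97% (3.14 to 4.93) in SOFT. Under the relative tag rule it was 14.9%, 17.3%, 9.69% and 10.4%, with STIFF above COL1 and SOFT above MATR. Under a margin rule, fixed in advance, that asks for a clear lead of 1 tag over the other, it was 8.03%, 14.1%, 5.07% and 10.3%. HR-positive cells made up 33.7% (31.3 to 36.1) of COL1, 44.0% (42 to 46.0) of STIFF, 53.3% (51.2 to 55.3) of MATR and 52.5% (50.2 to 54.7) of SOFT cells. Under the relative tag rule these shares were 29.8%, 29.4%, 44.8% and 44.9%, and under the margin rule 48.6%, 24.1%, 62.1% and 42.9%. HR-negative cells made up 11.3% (9.74 to 12.9) of COL1, 7.67% (6.65 to 8.80) of STIFF, 13.3% (12 to 14.8) of MATR and 11.3% (9.96 to 12.8) of SOFT. Under the relative tag rule these shares were 17.1%, 22.5%, 24.1% and 22.2%, and under the margin rule 3.75%, 20.7%, 5.21% and 23.7%. Clustering each pool alone put the HR-negative share at 20.03% in COL1 and 27.3% in STIFF. A cluster of 651 cells that also carried HR-positive markers was then named HR-negative. Fibroblast-like cells were 10.5% (9.02 to 12.1) of COL1 and 6.16% (5.24 to 7.19) of STIFF. They were 4.50% (3.70 to 5.42) of MATR and 4.22% (3.37 to 5.22) of SOFT cells. Immune-like cells were 9.28% (7.88 to 10.8), 10.1% (8.91 to 11.3), 6.56% (5.59 to 7.64) and 13.2% (11.8 to 14.8) in the same order. The relative tag rule put them at 7.87%, 4.74%, 4.96% and 6.11%, and the margin rule at 18.1%, 4.01%, 10.1% and 6.12%. At a coarser clustering, with no low-depth cluster set apart, the COL1 share was 14.3%. These shares describe tagged cells, and their order between conditions was not settled.

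**Figure D1:**
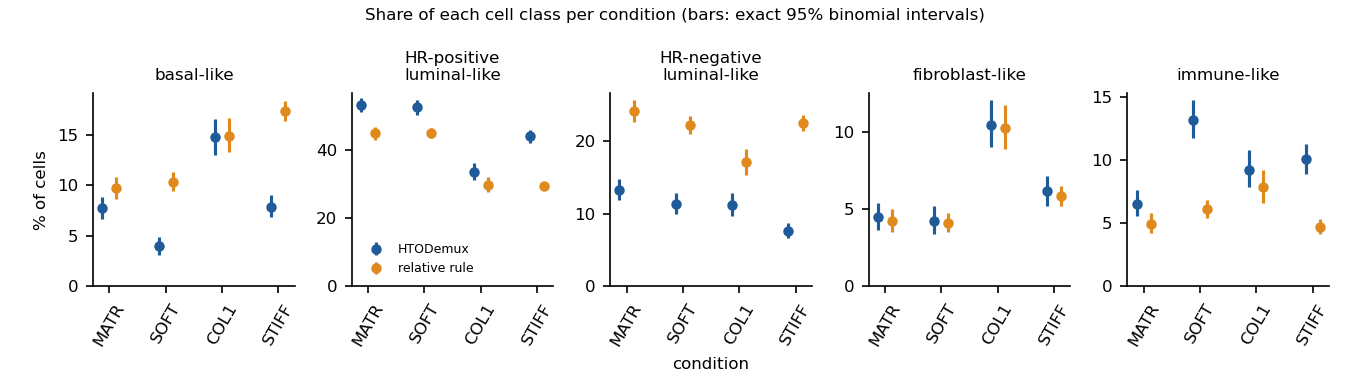
Share of cells (%) of each class in the 4 conditions, as points with exact 95% binomial intervals, under the HTODemux calls and under the relative tag rule. The basal-like share in STIFF was 7.87% by the first and 17.3% by the second.

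The HR-positive class was made of different clusters in different conditions. Cluster 1 held 178 of its 526 COL1 cells, 725 of 1078 STIFF cells, 811 of 1243 MATR cells and 203 of 1019 SOFT cells. Cluster 2 held 91, 7, 144 and 214 of them, and cluster 4 held 257, 346, 288 and 602. Klk1b27, Defb14, Krt4, Krt78 and Sprr2f were among the 10 leading genes of cluster 1, which held most HR-positive cells of MATR and STIFF. Reg3b, Calcb and Ffar4 were among those of cluster 4. Differences in these genes between conditions are therefore not independent of the clusters, whose sizes are not compared. Luminal transcripts were also counted in classes that should lack them, and free RNA and mixed cells were not separated. The luminal keratin Krt8 reached 306 CPM (counts scaled to a common total) in COL1 and 747 CPM in STIFF fibroblast-like cells, and 493 and 1222 CPM in immune-like cells. Below, background means the lowest level of a gene in another class of the same condition.

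COL1 over MATR asks how cells in collagen differ from those in Matrigel. Over all singlets the collagenase gene Mmp13 (65.1 and 4.18 CPM, 15.6-fold, 13.4 to 18.3), the neutrophil chemokine Cxcl2 (407 and 75.6 CPM, 5.39-fold, 5.18 to 5.61) and the matrix glycoprotein Tnc (111 and 25.4 CPM, 4.38-fold, 4.08 to 4.70) were higher in COL1. Brackets hold the level in the first and in the second condition, the fold between them and its 95% interval. The chemokines Cxcl1 (157 and 36.2 CPM), Ccl2 (327 and 93.1 CPM), Ccl3 (94.9 and 26.1 CPM) and Ccl6 (98.0 and 29.8 CPM) and the platelet factor Pf4 (163 and 36.1 CPM) were higher as well. Immune-like cells were 9.28% of COL1 and 6.56% of MATR cells, so values over all singlets can follow this share. Fabp4, Cck and Rarres2 were 3.12- to 5.31-fold higher. Lower in COL1 were the coagulation tissue factor F3 (120.4 and 393 CPM, 3.27-fold, 3.14 to 3.40) and the keratins Krt78 (45.6 and 158 CPM, 3.47-fold, 3.25 to 3.70), Krt4 (93.8 and 265 CPM, 2.83-fold, 2.70 to 2.96) and Krt79 (21.9 and 65.7 CPM). The defensin Defb14 (17.9 and 57.4 CPM), the alarmin Il33 (22.8 and 61.0 CPM), the glutathione peroxidase Gpx3 (196 and 432 CPM) and the iron-binding milk protein Ltf (172 and 330.3 CPM) were lower too. Mlph, Ttc36, Prom2 and Pdzk1ip1 were 1.88- to 2.08-fold lower. Summed over luminal-like cells alone, Fabp4 and Cck were at log2 ratios of -0.01 and -0.11, and over basal-like cells alone Mmp13 was at -0.05 and Il33 at 0.16. With tags ignored, the COL1 and STIFF pool over the MATR and SOFT pool gave -0.41 for Pf4, 0.83 for Defb14, 1.21 for Gpx3 and 0.18 for Prom2.

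Each gene list is given as its members' median log2 ratio, with the number of measured members at least 1.5-fold higher and lower in brackets, or for marker, keratin and milk protein lists the percentile alone. The percentile places the median among those of 10000 random lists of matched expression, and a list stood apart where it fell outside their central 95%. Fibrillar and interstitial matrix genes were at 0.92 (11 of 16 higher, 0 lower, percentile 100) over all singlets, led by Tnc at 1.78 and Fn1 at 1.26, while fibroblast-like cells were 10.5% of COL1 and 4.50% of MATR cells. Within fibroblast-like cells the same list was at -0.16 (2 of 16 higher, 3 lower, percentile 0.15), and within basal-like cells alone it was at -0.10. Matrix remodelling genes were at 0.79 (13 of 18 higher, 0 lower, percentile 100) and NF-kB and inflammatory genes at 0.64 (7 of 11 higher, 1 lower, percentile 100) over all singlets, beside the higher immune-like share of COL1.

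Immediate early genes are induced by stimuli within minutes, and their medians lay above the random range in each class compared, though few members were 1.5-fold higher in several. The AP-1 list was at 0.60 (4 of 8 higher, 0 lower, percentile 100) in basal-like cells, from Fosb at 1.11 and Atf3 at 0.96 down to Fosl2 at 0.39 and Jund at 0.29. It was at 0.32 (2 of 9 higher, 0 lower, percentile 100) in HR-positive, 0.38 (2 of 8 higher, 0 lower, percentile 100) in HR-negative, 0.35 (2 of 9 higher, 0 lower, percentile 99.99) in fibroblast-like and 0.58 (4 of 9 higher, 0 lower, percentile 100) in immune-like cells. None of its members reached 3 times background in basal-like cells and at most 2 did in any other class, so free RNA stays open as a source. The other immediate early genes were at 0.56 (5 of 12 higher, 0 lower, percentile 100) in basal-like, 0.23 (2 of 11 higher, 0 lower, percentile 99.87) in HR-positive, 0.29 (4 of 12 higher, 0 lower, percentile 100) in HR-negative, 0.27 (2 of 12 higher, 1 lower, percentile 99.99) in fibroblast-like and 0.73 (8 of 12 higher, 0 lower, percentile 100) in immune-like cells. In the last, where luminal markers were at -0.33 (percentile 0.07), or 0.35 without the cells of highest doublet score, Klf4 at 1.03 and Klf2 at 1.03 were highest and Dusp1 at 0.33 and Btg2 at 0.18 lowest. NF-kB and inflammatory genes were at 0.36 (1 of 9 higher, 0 lower, percentile 99.99) in basal-like, 0.27 (4 of 10 higher, 0 lower, percentile 100) in HR-negative and 0.41 (5 of 11 higher, 1 lower, percentile 100) in immune-like cells, with Cxcl1 at 2.09 and Cxcl2 at 1.63 highest in the last. The interferon response was lower in fibroblast-like cells, -0.80 (0 of 12 higher, 9 lower, percentile 0), with Ifit3 at -1.76 and Ifit1 at -1.53, and in immune-like cells, -0.43 (0 of 12 higher, 2 lower, percentile 0). In HR-positive cells it was at -0.05 (0 of 10 higher, 0 lower, percentile 2.57). Fibroblast-like cells also had contractile genes at 0.63 (8 of 14 higher, 0 lower, percentile 100), with Cnn1 at 1.24 and Myl9 at 0.89, and pericyte markers at -0.31 (percentile 1.34), so a changed mix of fibroblasts and pericytes was not excluded. The same cells had hypoxia and glycolysis genes at 0.35 (6 of 17 higher, 0 lower, percentile 100), with Slc2a1 at 0.80 and Ankrd37 at 0.70. HR-negative cells had hypoxia genes at -0.15 (0 of 17 higher, 2 lower, percentile 0.185).

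In basal-like cells the acute phase genes Saa2 (214 and 43.7 CPM, 4.89-fold, 4.04 to 5.97) and Saa1 (529 and 178 CPM) and the vasoactive peptide gene Adm (79.6 and 26.6 CPM, 2.99-fold, 2.30 to 3.92) were higher in COL1. Klf4 and Fosb were 2.19- to 2.29-fold higher at less than 3 times background. The luminal genes Ltf (51.7 and 177 CPM, 3.43-fold, 2.85 to 4.15), Krt4 (13.7 and 60.4 CPM) and Gpx3 (45.4 and 154 CPM) were lower, as were Igfbp2 (54.9 and 154 CPM) and, near background, F3 and Krt19. Without the cells of highest doublet score Ltf, Krt4, Gpx3 and Krt19 were at log2 ratios of -0.33, -0.75, -0.51 and -0.39, against -1.60, -1.57, -1.56 and -1.20 with them. HR-positive marker genes were at -0.32 (percentile 0) in these cells. G2/M phase genes were lower in COL1 basal-like cells, -0.63 (0 of 15 higher, 8 lower, percentile 0), with Mki67 at -0.86 and Top2a at -0.85. Contractile genes were at -0.24 (0 of 13 higher, 1 lower, percentile 0.01). HR-positive cells, mostly of clusters 4 and 1 in COL1 and of cluster 1 in MATR, held more of the antimicrobial lectin Reg3b (80.0 and 11.5 CPM, 6.97-fold, 5.92 to 8.24) and of Clca3a2 (340.5 and 117 CPM), Calcb (73.2 and 20.7 CPM), Serpine2 (96.3 and 34.6 CPM) and Cp (103 and 39.3 CPM) in COL1. Reg3b was at a log2 ratio of 0.65 under the margin rule, against 2.07. Lcn2, at 1031 and 432 CPM, was at background, with 22785 CPM in COL1 HR-negative cells. F3, Il33, Krt78, Krt79, Defb14 and Krt4 were 2.28- to 2.79-fold lower in COL1 HR-positive cells. Integrins and focal adhesion genes were at 0.22 (1 of 18 higher, 0 lower, percentile 99.87) there, with Itga2 at 0.71 and Itgb1 at 0.45 highest, and matrix remodelling genes at 0.32 (2 of 9 higher, 0 lower, percentile 99.98), with Serpine2 at 1.25 and Mmp14 at 0.65. Contractile genes were at 0.44 (2 of 7 higher, 0 lower, percentile 100), none of them at 3 times background. In HR-negative cells Cxcl1 (98.0 and 31.1 CPM) was higher, and Cbr2 (27.0 and 81.2 CPM), Arg1 (24.7 and 56.5 CPM), Thbs1 (221 and 402 CPM), Adig (32.4 and 63.5 CPM), Wfdc2 (482 and 826 CPM) and Ltf (673 and 1085 CPM) were lower. Hbegf, Klf4, Tuba1a, Hist1h1c and Nfkbia were 2.24- to 2.66-fold higher, at less than 3 times background. Condition and channel cannot be told apart in this comparison.

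STIFF over SOFT asks how cells in a stiff matrix differ from those in a soft one. The kallikrein gene Klk1b27 (186 and 1.72 CPM, 108-fold, 84.8 to 141), the kallikrein Klk1 (50.4 and 2.20 CPM, 22.9-fold, 18.4 to 28.9), the defensin Defb14 (85.2 and 7.25 CPM, 11.8-fold, 10.4 to 13.3) and the glutathione peroxidase Gpx3 (819 and 116 CPM, 7.06-fold, 6.84 to 7.29) were higher in STIFF. Sprr2f, Calca, Tnxb, Defb1, Smim38, Acot1 and Cdo1 were 2.92- to 5.17-fold higher, and the basal keratin Krt5 (66.3 and 19.3 CPM, 3.44-fold, 3.17 to 3.73) was higher beside a basal-like share of 7.87% in STIFF and 3.97% in SOFT. Lower in STIFF were the hypoxia-induced genes Ndrg1 (120.0 and 304 CPM, 2.53-fold, 2.45 to 2.61) and Ero1l (130.4 and 291 CPM, 2.23-fold, 2.17 to 2.30), while the hypoxia and glycolysis list was at 0.03 (0 of 17 higher, 1 lower, percentile 68.97), or -0.13 under the relative tag rule. Also lower were the metallothioneins Mt1 (962 and 2041 CPM) and Mt2 (178 and 400.2 CPM), haem oxygenase Hmox1 (39.1 and 99.3 CPM), the fatty acid receptor Ffar4 (56.7 and 151 CPM) and the chemokine Cxcl14 (117 and 279.9 CPM). The interferon-induced Ifi27l2a (74.1 and 165 CPM) and the macrophage genes Pf4 (40.1 and 208 CPM), Cd52 (75.4 and 160.3 CPM), F13a1 (20.8 and 50.8 CPM) and Gatm were lower too, beside an immune-like share of 10.1% in STIFF and 13.2% in SOFT. Over basal-like cells alone, 77 of them in SOFT, Defb1, Pf4, Cxcl14, Gatm and F13a1 turned to log2 ratios of -0.22, 0.09, 0.09, 0.21 and 0.58, and over luminal-like cells alone Cd52 turned to 0.05. Under the relative tag rule Sprr2f and Defb1 were at 0.98 and 0.97, against 1.91 and 1.59.

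In HR-positive cells, mostly of cluster 1 in STIFF and cluster 4 in SOFT, Klk1b27 (394 and 0.884 CPM, 445-fold, 260.3 to 837), Klk1 (123 and 3.40 CPM, 36.1-fold, 27.3 to 48.9), Gpx3 (1622 and 196 CPM), Defb14 (165 and 14.7 CPM), Tnxb (114 and 20.9 CPM) and Sprr2f (569 and 138 CPM) were higher in STIFF. Ndrg1 (109 and 381 CPM), Mt2 (216 and 633 CPM), Mt1 (1125 and 3086 CPM), Ffar4 (111 and 307 CPM), Ero1l (161 and 429 CPM) and Igfbp7 were lower, of which Mt1, Ero1l and Igfbp7 were below 3 times background. AP-1 genes were at 0.29 (3 of 9 higher, 0 lower, percentile 99.98) in this class, with Atf3 at 1.40 and Fosb at 1.14 highest and Junb at -0.16 and Fosl2 at -0.23 lowest, and other immediate early genes at 0.45 (5 of 11 higher, 0 lower, percentile 100). The hypoxia and glycolysis list was at 0.10 (0 of 17 higher, 1 lower, percentile 95.69) in these cells. Interferon genes were at -0.40 (0 of 11 higher, 2 lower, percentile 0), integrins and focal adhesion genes at -0.24 (0 of 18 higher, 2 lower, percentile 0) and TGF-beta targets at -0.24 (0 of 11 higher, 4 lower, percentile 0.05). YAP/TEAD targets, which answer to mechanical load, were at -0.20 (0 of 12 higher, 3 lower, percentile 0.02), with Crim1 at -1.34 and Ccn2 at -0.79 lowest and Ccn1 at 0.07 and F3 at 0.06 highest. Beside them contractile genes were at -0.30 (0 of 7 higher, 2 lower, percentile 0.04) and basal keratins at -0.43 (percentile 0.43), so mixed cells stay open. In HR-negative cells YAP/TEAD targets were at -0.20 (0 of 13 higher, 1 lower, percentile 0.145). In the same cells, where basal markers were at 1.08 (percentile 100), AP-1 genes were at 0.72 (4 of 8 higher, 0 lower, percentile 100) and other immediate early genes at 0.52 (5 of 12 higher, 0 lower, percentile 100). The stress factors Atf3 (599 and 160.2 CPM, 3.74-fold, 3.49 to 4.0), Klf6 (1049 and 306 CPM) and Klf2 (652 and 195 CPM) and the peptide hormone gene Cck (52.7 and 7.01 CPM) were higher in STIFF HR-negative cells. The actin-binding Tagln (67.7 and 12.1 CPM) was higher as well, at a log2 ratio of 1.81, or 0.63 under the relative tag rule, and Gpx3, at 74.3 and 11.2 CPM, was below background. NF-kB and inflammatory genes were at 0.62 (5 of 9 higher, 1 lower, percentile 100), interferon genes at -0.32 (0 of 12 higher, 3 lower, percentile 0) and milk protein genes at 0.78 (percentile 100), led by Lalba at 1.14 and Csn1s1 at 1.09. Hypoxia and glycolysis genes were at -0.47 (0 of 17 higher, 4 lower, percentile 0), with Adm at -0.89 and Ndrg1 (136 and 383 CPM, 2.81-fold, 2.6 to 3.05). Timp3 (40.8 and 121 CPM), Hrct1 (43.9 and 123 CPM), Espn (21.4 and 66.4 CPM), Foxq1 (20.4 and 55.9 CPM) and Hmox1 were lower in these cells. Immune-like cells, where luminal markers were at 1.61 (percentile 100), had AP-1 genes at 0.63 (5 of 9 higher, 0 lower, percentile 99.96) and other immediate early genes at 0.40 (3 of 12 higher, 0 lower, percentile 99.9). There YAP/TEAD targets were at 0.55 (5 of 11 higher, 0 lower, percentile 99.96), integrins and focal adhesion genes at 0.42 (6 of 19 higher, 0 lower, percentile 99.97) and TGF-beta targets at 0.35 (5 of 14 higher, 1 lower, percentile 99.55). Interstitial matrix genes at 1.27 (13 of 15 higher, 1 lower, percentile 100) and milk protein genes at 2.13 (percentile 100), made by other classes, were higher beside them, so RNA from other cells was not excluded.

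SOFT held fewer than 100 basal-like and fewer than 100 fibroblast-like cells by the main tag calls. These classes of STIFF and SOFT, and of MATR and SOFT, were therefore compared under the relative tag rule, with 932 STIFF, 287 MATR and 432 SOFT basal-like cells. In STIFF over SOFT basal-like cells AP-1 genes were at 0.65 (4 of 8 higher, 0 lower, percentile 100), with Fosb at 1.36 and Atf3 at 1.14 highest, and other immediate early genes at 0.73 (7 of 12 higher, 0 lower, percentile 100). Of these genes 0 of 8 and 3 of 12 reached 3 times background. YAP/TEAD targets were at 0.02 (1 of 14 higher, 0 lower, percentile 52.05) in basal-like cells. Hypoxia and glycolysis genes were at -0.42 (0 of 17 higher, 6 lower, percentile 0), among them the oxygen-sensing hydroxylase Egln3 (38.1 and 120.3 CPM, 3.16-fold, 2.77 to 3.61) and Adm at -1.55. The collagen hydroxylase P4ha2 (18.4 and 75.4 CPM), the placental growth factor Pgf (42.4 and 129 CPM), Espn (20.7 and 108 CPM), Sprr2a3 (11.5 and 53.7 CPM) and, near background, Ero1l were lower as well. Interstitial matrix genes were at 0.37 (5 of 16 higher, 0 lower, percentile 100), with Fn1 at 0.96 and Col6a1 at 0.71, and basal keratins at 0.60 (percentile 99.93). Of the genes that luminal cells express, Sprr2f (101 and 2.43 CPM, 41.6-fold, 22.5 to 87.0), Saa1 (275 and 52.3 CPM), Saa2 (115 and 22.1 CPM), Csn3 (712 and 186 CPM), Gpx3 (129 and 34.5 CPM) and Lrg1 (65.6 and 15.3 CPM) were higher in STIFF. HR-negative markers were at 0.67 (percentile 100) and luminal keratins at -0.09 (percentile 25.15). With cells weighted equally Sprr2f, Saa1 and Gpx3 were at log2 ratios of 2.32, 1.51 and 1.04, against 3.16, 2.19 and 1.64. In fibroblast-like cells hypoxia genes were at -0.48 (0 of 17 higher, 8 lower, percentile 0). Condition and channel cannot be told apart in STIFF over SOFT either.

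COL1 over STIFF compares the collagen and the stiff culture within 1 channel. Over all singlets the macrophage gene Pf4 (163 and 40.1 CPM, 4.05-fold, 3.84 to 4.28), the collagenase Mmp13 (65.1 and 17.1 CPM, 3.80-fold, 3.50 to 4.13) and the hypoxia-induced Ndrg1 (251 and 120.0 CPM, 2.09-fold, 2.02 to 2.16) were higher in COL1. Fabp4, Cck, Rarres2, F13a1, Aebp1, Cryab and Mfap5 were 2.11- to 2.87-fold higher. Lower in COL1 were Klk1b27 (12.7 and 186 CPM, 14.7-fold, 13.1 to 16.5), Gpx3 (196 and 819 CPM, 4.17-fold, 4.05 to 4.30), the growth factor Ptn (55.3 and 197 CPM, 3.56-fold, 3.36 to 3.78), Defb14 (17.9 and 85.2 CPM), Tnxb (18.3 and 62.9 CPM) and Klk1 (14.7 and 50.4 CPM). Smim38, Acot1, Cdo1, Hist1h4i, Gsta4 and Cited1 were 1.83- to 2.90-fold lower. Over luminal-like cells alone Cck turned to a log2 ratio of -0.45, and over basal-like cells alone Cck, Rarres2 and F13a1 turned to -0.09, -0.32 and -0.53. Under the margin rule Mmp13 was at 0.84, against 1.47. In HR-positive cells, mostly of clusters 4 and 1 in COL1 and of cluster 1 in STIFF, Klk1b27 (16.2 and 394 CPM, 24.3-fold, 20.1 to 29.7), Gpx3 (353 and 1622 CPM), Ptn (108 and 420.0 CPM), Defb14 (39.7 and 165 CPM), Tnxb (32.9 and 114 CPM) and Klk1 (36.4 and 123 CPM) were lower in COL1. Ndrg1 (357 and 109 CPM, 3.28-fold, 3.08 to 3.50), Ero1l (404 and 161 CPM), the gap junction gene Gja1 (191 and 74.1 CPM), Mt2 (496 and 216 CPM), Mt1 (2343 and 1125 CPM) and Ffar4 (261 and 111 CPM) were higher there.

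Hypoxia and glycolysis genes were higher in COL1 than in STIFF in basal-like cells, at 0.39 (5 of 17 higher, 0 lower, percentile 100), and in fibroblast-like cells, at 0.37 (7 of 17 higher, 0 lower, percentile 100). They were at 0.13 (0 of 17 higher, 0 lower, percentile 99.86) in HR-negative and 0.01 (1 of 17 higher, 0 lower, percentile 58.79) in HR-positive cells. In basal-like cells Adm (79.6 and 12 CPM, 6.63-fold, 4.84 to 9.25), Egln3 (124 and 39.0 CPM, 3.17-fold, 2.62 to 3.85), the angiogenic factor Vegfa (277 and 111 CPM, 2.49-fold, 2.21 to 2.8), the oxidase Nox4 (102 and 34.0 CPM), Espn (72.2 and 21.7 CPM) and Fxyd4 (82.4 and 28.0 CPM) were higher in COL1. Sprr2f (3.52 and 163 CPM, 46.3-fold, 25 to 97.0), Klk1b27 (1.06 and 73.7 CPM), Gpx3 (45.4 and 319.7 CPM), fibronectin Fn1 (19.0 and 99.2 CPM), Ptn (44.7 and 195 CPM) and Krt4 (13.7 and 55.0 CPM) were lower. Of these, Klk1b27, Gpx3, Ptn and Krt4 were at log2 ratios of -0.20, -1.28, -0.65 and -0.78 without the cells of highest doublet score, against -2.92, -2.57, -1.91 and -1.45. Adm and Egln3 were at 2.96 and 2.05, against 2.03 and 1.45. AP-1 genes did not stand apart in basal-like, 0.05 (0 of 8 higher, 0 lower, percentile 75.78), or HR-positive cells, 0.00 (0 of 9 higher, 0 lower, percentile 47.43). They were at -0.18 (0 of 8 higher, 0 lower, percentile 0.84) in HR-negative cells, which turned to 0.05 under the relative tag rule, and at 0.16 (0 of 9 higher, 0 lower, percentile 98.2) in immune-like cells. Other immediate early genes were at 0.01 (0 of 12 higher, 0 lower, percentile 65.92) in basal-like, 0.00 (0 of 11 higher, 0 lower, percentile 52.2) in HR-positive, 0.20 (0 of 12 higher, 0 lower, percentile 99.99) in HR-negative and 0.32 (1 of 12 higher, 0 lower, percentile 100) in immune-like cells, where luminal markers were at -1.02 (percentile 0).

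HR-positive marker genes were at -0.81 (percentile 0) in basal-like cells, which had luminal keratins at -0.77 (percentile 0), against -0.10 under the relative tag rule, and basal keratins at -0.44 (percentile 0.22). HR-positive cells had integrins and focal adhesion genes at 0.11 (1 of 18 higher, 0 lower, percentile 99.33), TGF-beta targets at 0.12 (3 of 12 higher, 0 lower, percentile 99.05), YAP/TEAD targets at 0.12 (2 of 12 higher, 0 lower, percentile 99.07) and interferon genes at -0.07 (0 of 11 higher, 2 lower, percentile 10.97). In fibroblast-like cells interferon genes were at -0.60 (0 of 12 higher, 6 lower, percentile 0) and matrix remodelling genes at 0.35 (4 of 18 higher, 0 lower, percentile 100), with Mmp13 at 2.05 highest. S and G2/M phase genes were at -0.50 (0 of 16 higher, 6 lower, percentile 0) and -0.42 (0 of 18 higher, 6 lower, percentile 0) in these cells. In HR-negative cells Hrct1 (95.2 and 43.9 CPM), Sparcl1 (310.2 and 158 CPM), Ifi27l2a (184 and 107 CPM), Clca3a2 (217 and 133 CPM), Cyp1b1 (63.1 and 36.3 CPM) and, near background, Ddit4 were higher in COL1 and Bglap3 (41.5 and 102 CPM), Tagln (27.6 and 67.7 CPM) and Cck (24.1 and 52.7 CPM) lower. Areg, Gpx3 and Pcp4 were lower at levels below background. Bglap3 was at a log2 ratio of -0.33 under the relative tag rule and Tagln at -0.12 with cells thinned, against -1.12 and -1.05. Milk protein genes were at -0.24 (percentile 0.04) and basal markers at -0.62 (percentile 0) in this class.

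MATR over SOFT compares Matrigel and the soft matrix within 1 channel. The immune-like share was 6.56% in MATR and 13.2% in SOFT but 10.1% and 6.12% under the biased margin rule. Macrophage genes were lower in MATR over all singlets. Among them were the lysozyme gene Lyz2 (1470 and 4439 CPM, 3.02-fold, 2.99 to 3.05), the chemokines Ccl6 (29.8 and 206 CPM, 6.93-fold, 6.53 to 7.35), Cxcl2 (75.6 and 354 CPM, 4.68-fold, 4.50 to 4.86), Ccl2 (93.1 and 332 CPM) and Ccl3 (26.1 and 95.4 CPM), Pf4 (36.1 and 208 CPM) and the interleukin Il1b (29.1 and 128 CPM). Srgn, S100a4, Cxcl14, Apoc2 and Tgfbi were 3.07- to 3.66-fold lower. Under the margin rule Lyz2 was at a log2 ratio of -0.25, Cxcl2 at -0.80 and Ccl6 at -1.34, against -1.59, -2.09 and -2.44. Over luminal-like cells alone Ccl6, Il1b, Ccl3 and Tgfbi turned to 0.04, 0.09, 0.02 and 0.03, and over basal-like cells alone, again 77 in SOFT, Pf4 and Apoc2 turned to 0.25 and 0.31. Higher in MATR were Defb14 (57.4 and 7.25 CPM, 7.92-fold, 6.98 to 9.01), Gpx3 (432 and 116 CPM, 3.73-fold, 3.61 to 3.85), Krt78 (158 and 38.4 CPM, 4.12-fold, 3.89 to 4.36) and Krt4 (265 and 86.7 CPM, 3.06-fold, 2.94 to 3.18). Krt79, Sprr2f, Prom2, F3, Cxcl15, Pdzk1ip1, Mlph and Mgp were 2.25- to 3.22-fold higher. Mgp turned to -0.40 under the margin rule, from 1.18. In HR-positive cells, mostly of cluster 1 in MATR and cluster 4 in SOFT, Defb14 (107 and 14.7 CPM), Gpx3 (765 and 196 CPM), Krt78 (269.9 and 73.8 CPM), Krt4 (481 and 176 CPM), Krt79 (116 and 41.2 CPM) and F3 (684 and 284 CPM) were higher. Reg3b (11.5 and 92.7 CPM, 8.08-fold, 6.97 to 9.41), Calcb (20.7 and 91.1 CPM), Dusp2 (13.1 and 72.1 CPM) and the chaperone clusterin, Clu (1091 and 3089 CPM, 2.83-fold, 2.78 to 2.88), were lower. Lcn2 and Cald1 were lower at background levels.

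Interferon genes were lower in MATR HR-positive cells, at -0.60 (0 of 10 higher, 6 lower, percentile 0), with Rtp4 at -0.75 and Ifi44 at -0.75. In the same class TGF-beta targets were at -0.32 (1 of 11 higher, 1 lower, percentile 0), integrins and focal adhesion genes at -0.24 (0 of 18 higher, 2 lower, percentile 0), with Itga2 at -0.75 and Zyx at -0.64 lowest, and YAP/TEAD targets at -0.22 (1 of 12 higher, 1 lower, percentile 0.03). Matrix remodelling genes were at -0.37 (0 of 10 higher, 4 lower, percentile 0), contractile genes at -0.36 (0 of 7 higher, 3 lower, percentile 0.01) and hypoxia and glycolysis genes at 0.25 (1 of 17 higher, 0 lower, percentile 100). AP-1 genes were at 0.01 (0 of 9 higher, 0 lower, percentile 62.21) in HR-positive cells and at 0.41 (2 of 8 higher, 0 lower, percentile 100) in HR-negative cells, with Fosb at 0.84 and Atf3 at 0.62 highest in the latter. Other immediate early genes were at 0.17 (1 of 11 higher, 0 lower, percentile 99.81) and 0.53 (5 of 12 higher, 0 lower, percentile 100) in these classes. HR-negative cells had milk protein genes at 0.62 (percentile 100) and hypoxia genes at -0.17 (0 of 17 higher, 0 lower, percentile 0.005). The carbonyl reductase Cbr2 (81.2 and 22.8 CPM), Pdzk1ip1 (179 and 69.5 CPM), Atp6v1b1 (243 and 120.5 CPM), Egr2, Btg2 and Klf6 were higher in MATR HR-negative cells, and Foxq1 (13.4 and 55.9 CPM), Timp3 (50.8 and 121 CPM) and Tcim (223 and 399.8 CPM) were lower. Igfbp7, Hmox1 and Ddit4 were lower near background. In basal-like cells AP-1 genes were at 0.11 (0 of 8 higher, 0 lower, percentile 97.68), hypoxia genes at -0.07 (0 of 17 higher, 1 lower, percentile 8.695) and interstitial matrix genes at 0.34 (2 of 16 higher, 1 lower, percentile 100). The milk genes Ltf (145 and 13.4 CPM), Wfdc18 (550.1 and 149 CPM) and Csn3 (531 and 186 CPM), Dcn (261 and 74.1 CPM), Gpx3 (110.2 and 34.5 CPM) and Saa1 (144 and 52.3 CPM) were higher there, beside HR-negative markers at 0.91 (percentile 100) and luminal keratins at 0.06 (percentile 84.77). With cells weighted equally Ltf, Wfdc18, Csn3 and Saa1 were at log2 ratios of 1.498, 0.91, 0.66 and 0.29, against 2.73, 1.82, 1.47 and 1.31. The epidermal protease gene Klk8 (33.0 and 97.2 CPM), the keratin Krt17 (287 and 595 CPM), Gpx2 (99 and 193 CPM), Clu (206 and 379 CPM), P4ha2 (36.3 and 75.4 CPM) and Hspa4l (21.8 and 53.2 CPM) were lower. In immune-like cells luminal markers were at 0.95 (percentile 100), contractile genes at 0.73 (6 of 10 higher, 0 lower, percentile 100), interstitial matrix genes at 0.65 (8 of 15 higher, 2 lower, percentile 100), luminal keratins at 1.02 (percentile 100) and milk protein genes at 0.46 (percentile 99.94), which turned to -0.23 under the margin rule. The same cells had AP-1 genes at 0.28 (1 of 9 higher, 0 lower, percentile 98.98) and other immediate early genes at -0.16 (0 of 12 higher, 0 lower, percentile 1.08). Fibroblast-like cells had hypoxia genes at -0.40 (0 of 17 higher, 4 lower, percentile 0).

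**Figure D2:**
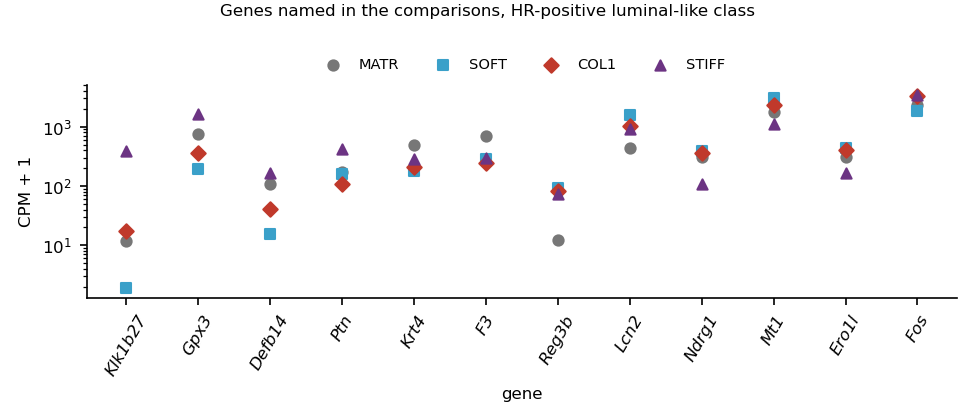
Summed level (CPM + 1, log axis) of 12 genes in HR-positive luminal-like cells of each condition, 1 marker per condition, with the genes chosen from those named in the comparisons after their values were seen. Klk1b27 was at 394 CPM in STIFF, 16.2 in COL1 and 0.884 in SOFT.

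**Figure D3:**
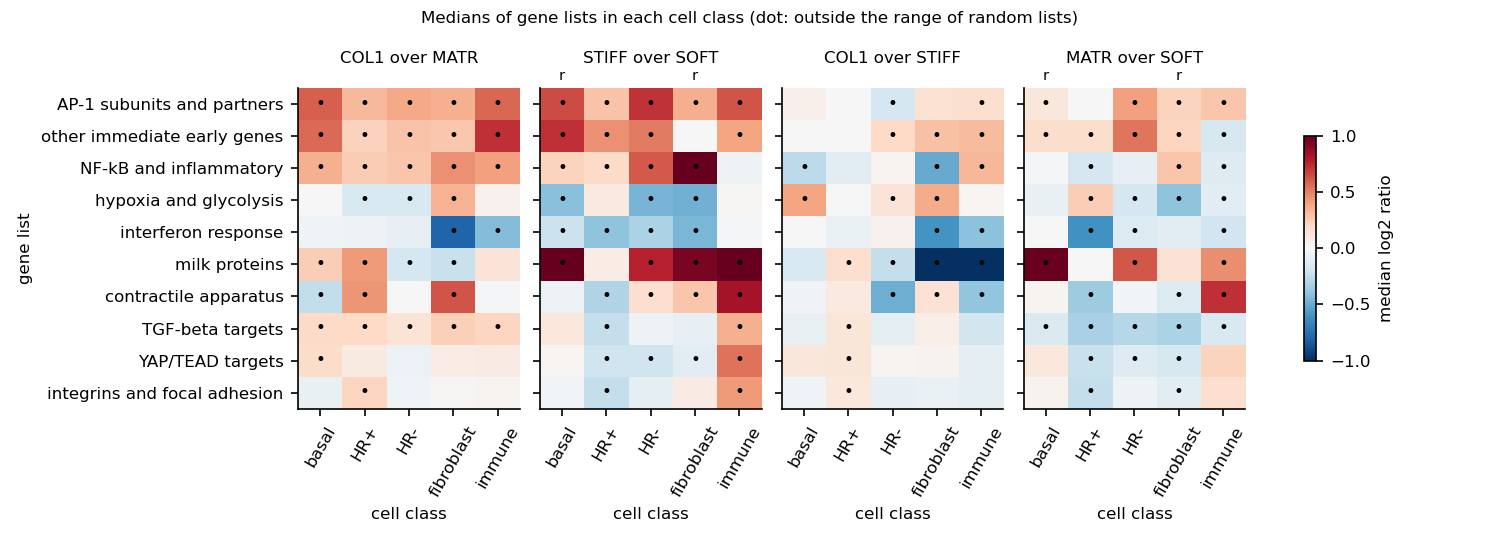
Median log2 ratio of 10 gene lists (lists down, cell classes across) in the 4 comparisons, on a colour scale that ends at -1 and 1, where a dot marks a median outside the central 95% of random lists and r a column under the relative tag rule. The AP-1 list in HR-negative cells was at 0.72 in STIFF over SOFT and 0.41 in MATR over SOFT.

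The AP-1 subunits differed widely in level. Over all singlets Fos was at 3618 CPM in COL1, 3622 in STIFF, 2632 in MATR and 1914 in SOFT. In the same order Fosb was at 651, 650.2, 417 and 284 CPM, and Atf3 at 469, 599, 314 and 250.2 CPM. Jun was at 2206, 2285, 1961 and 1617 CPM, Junb at 1647, 1401, 1396 and 1341 CPM, and Jund at 1394, 1629, 1533 and 1312 CPM. The scarcer Fosl2 was at 35.6, 37.0, 30.7 and 38.1 CPM, Fosl1 at 6.65, 3.54, 2.56 and 3.63 CPM, and the immune subunit Batf at 4.99, 6.27, 5.52 and 5.16 CPM. The list was at 0.27 (1 of 10 higher, 0 lower, percentile 99.92) in COL1 over MATR and 0.31 (3 of 9 higher, 0 lower, percentile 100) in STIFF over SOFT, both across channels. Within channels it was at -0.02 (0 of 10 higher, 0 lower, percentile 38.88) in COL1 over STIFF and 0.22 (0 of 9 higher, 0 lower, percentile 99.91) in MATR over SOFT, the last at -0.01 over basal-like cells alone by the main calls, with 77 SOFT cells, and at 0.11 (0 of 8 higher, 0 lower, percentile 97.68) in basal-like cells under the relative tag rule.

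Keratins of both lineages were measured in basal-like cells, since cells between lineages can hold both. Krt5 was at 481 CPM in COL1, 761 in STIFF, 580.0 in MATR and 482 in SOFT, and Krt14 at 1053, 1452, 957 and 1363 CPM. The luminal keratin Krt8 was at 539.6, 1034, 782 and 994 CPM and Krt18 at 743, 1140, 989.7 and 1198 CPM. Without the cells of highest doublet score Krt8 was at 350.0, 528, 327 and 573 CPM, and under the relative tag rule at 500.3, 591, 611 and 612 CPM. The luminal keratin list in COL1 over MATR basal-like cells was at -0.47 (percentile 0.05), and at 0.07 without the cells of highest doublet score. Krt8 levels in fibroblast-like and immune-like cells overlapped these, so free RNA and mixed cells stay open. After thinning each cell to 3000 UMIs, 70.7% (64.3 to 76.6) of COL1 basal-like cells held a UMI of Krt5 or Krt14 and of Krt8 or Krt18, 69.5% (62.4 to 75.9) of STIFF, 61.7% (54.1 to 68.8) of MATR and 65.3% (53.5 to 76.0) of SOFT. These shares were not compared. Too shallow to thin were 8 COL1, 3 STIFF, 0 MATR and 2 SOFT cells. Without thinning the shares were 93.0%, 98.4%, 97.2% and 93.5%, at median depths of 8642, 18830, 11778 and 13362 UMIs. In thinned fibroblast-like cells they were 5.77%, 7.33%, 5.94% and 3.70%, from unthinned medians of 14066, 20418, 17249 and 25344 UMIs. Fibroblasts should lack Krt5 and Krt14, so this cannot gauge stray Krt8 or Krt18.

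Cell cycle genes were measured because growth can differ between matrices. After thinning, 4.07% (3.12 to 5.22) of COL1 cells held a UMI of Mki67 or Top2a, 4.98% (4.15 to 5.92) of STIFF, 2.09% (1.54 to 2.76) of MATR and 3.96% (3.13 to 4.93) of SOFT cells, leaving out 115, 22, 32 and 23 shallow cells. Unthinned shares were 9.66%, 11.4%, 5.79% and 10.8%, at median depths of 11353, 16843, 14722 and 15233 UMIs. Both genes mark dividing cells of any class, so no class served as background, and free RNA stays open as a source. G2/M phase genes over all singlets were at 0.18 (0 of 14 higher, 0 lower, percentile 99.66) in COL1 over MATR, 0.24 (0 of 16 higher, 0 lower, percentile 100) in STIFF over SOFT, -0.20 (0 of 16 higher, 0 lower, percentile 0) in COL1 over STIFF and -0.15 (0 of 14 higher, 0 lower, percentile 0.06) in MATR over SOFT. Over basal-like cells alone they turned to -0.63 in COL1 over MATR, -0.37 in STIFF over SOFT and 0.08 in MATR over SOFT, where SOFT had 77 such cells. With the 432 SOFT cells of the relative tag rule the basal-like medians were -0.20 (0 of 16 higher, 0 lower, percentile 0) in STIFF over SOFT and 0.04 (0 of 17 higher, 0 lower, percentile 66.75) in MATR over SOFT. S phase genes were at 0.05 (0 of 12 higher, 0 lower, percentile 65.23), 0.12 (0 of 14 higher, 0 lower, percentile 99.4), -0.20 (0 of 14 higher, 0 lower, percentile 0) and -0.14 (0 of 14 higher, 0 lower, percentile 0.15) in the order of the comparisons, the last at 0.03 over luminal-like cells alone.

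For other lists the lowest and highest median over all singlets and the 3 epithelial classes are given. The basement membrane list ran from -0.26 in STIFF over SOFT HR-positive cells to 0.27 in COL1 over MATR singlets, which turned to -0.05 over basal-like and -0.02 over luminal-like cells alone. Epithelial-mesenchymal genes ran from -0.33 in MATR over SOFT HR-positive cells to 0.45 in COL1 over MATR singlets, where fibroblast-like cells were more frequent and the value over basal-like cells alone was -0.04. The Wnt list ran from -0.28 in MATR over SOFT HR-negative cells to 0.25 in COL1 over MATR singlets, which turned to -0.29 when only members of at least 20 CPM were used. The Notch list ran from -0.10 to 0.16, the unfolded protein response from -0.10 to 0.19, p53 targets from -0.16 to 0.14 (0.01 and -0.18 over basal-like cells alone, the second with 77 SOFT cells) and heat shock genes from -0.16 to 0.13. By the files' identifiers and the reference annotation of the GRCm38 build, the genes with the highest log2 ratio over all singlets in the 4 comparisons were Mmp13 (ENSMUSG00000050578, chromosome 9, 7272514 to 7283333), Klk1b27 (ENSMUSG00000063177, chromosome 7, 44052290 to 44056712), Pf4 (ENSMUSG00000029373, chromosome 5, 90772435 to 90773383) and Defb14 (ENSMUSG00000046354, chromosome 8, 19160244 to 19195309).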

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

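The search for gene lists with opposite directions was chosen only after the result was seen. Several gene lists lay on opposite sides of the random range in epithelial classes of the same comparison, under both tag rules, and the difference between the classes was not tested. In COL1 over MATR, contractile genes had a median log2 ratio of -0.24 (percentile 0.01) in basal-like and 0.44 (percentile 100) in HR-positive cells, where no member reached 3 times background. Milk protein genes in the same comparison were at 0.25 (percentile 99.83) in basal-like, 0.43 (percentile 100) in HR-positive and -0.18 (percentile 0.505) in HR-negative cells, and no member reached 3 times background in the HR-positive class. In MATR over SOFT, hypoxia and glycolysis genes were at 0.25 (percentile 100) in HR-positive and -0.17 (percentile 0.005) in HR-negative cells. In COL1 over STIFF, cholesterol synthesis genes were at -0.28 (percentile 0.02) in basal-like, 0.13 (percentile 99.38) in HR-positive and 0.24 (percentile 99.99) in HR-negative cells. Hashtag3, which no comparison used, had 12756 counts in kept barcodes of the COL1 and STIFF pool and 12874 in those of the MATR and SOFT pool, which was 0.381% and 0.339% of the Hashtag1 counts.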

How the results depend on the processing

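The relative tag rule, the exchange of tags in the MATR and SOFT pool and the removal of unnamed clusters or of the highest doublet scores were chosen only after the data were seen. Over all alternatives, 235 of the values that answer a comparison stayed within their counting interval, 111 moved beyond it and 2 turned around. A list median that had not stood apart counts as moved whatever its sign. The AP-1 median of COL1 over STIFF singlets was such a value, and its sign changed with tags exchanged in the COL1 and STIFF pool, under the relative tag rule, without unnamed clusters and over basal-like cells alone. Of the values for single genes and further lists, 3076 stayed, 1941 moved and 260 turned around. Of all values, 107 turned around with tags exchanged in the COL1 and STIFF pool and 105 in the other pool. Depth limited classes with few cells, and barcodes without a tag could not be used. Keeping the doublets of scrublet moved no value, because it had marked none. Class values were not computed where an alternative left fewer than 100 cells of the class in a condition, except that values over basal-like cells alone were computed for SOFT from its 77 basal-like cells by the main calls. Values below are those that turned around, and for results that answer a comparison also those that moved. Genes and lists are given as log2 ratios and classes as shares of cells. Where tags were exchanged the values follow from the exchange, and for all other settings the cause was not tested.

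Under the margin rule, the AP-1 list over all singlets was at 0.16 in COL1 over MATR, 0.22 in STIFF over SOFT, -0.095 in COL1 over STIFF and 0.13 in MATR over SOFT. In COL1, STIFF, MATR and SOFT the basal-like share was 8.03%, 14.1%, 5.07% and 10.3%, and the HR-positive share 48.6%, 24.1%, 62.1% and 42.9%. The HR-negative share was 3.75%, 20.7%, 5.21% and 23.7%, and the immune-like share 18.1%, 4.01%, 10.1% and 6.12%. The fibroblast-like share was 6.43% in COL1, 5.13% in STIFF and 2.74% in MATR. Mgp was at -0.40 in MATR over SOFT singlets. Wnt pathway genes were at -0.11 in COL1 over MATR singlets. Milk protein genes were at -0.23 in MATR over SOFT immune-like cells.

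Under the relative tag rule, the AP-1 list over all singlets was at 0.24 in STIFF over SOFT, 0.032 in COL1 over STIFF and 0.20 in MATR over SOFT. The basal-like share was 17.3% in STIFF, 9.69% in MATR and 10.4% in SOFT. In COL1, STIFF, MATR and SOFT the HR-positive share was 29.8%, 29.4%, 44.8% and 44.9%, and the HR-negative share 17.1%, 22.5%, 24.1% and 22.2%. The immune-like share was 7.87%, 4.74%, 4.96% and 6.11%. AP-1 genes were at 0.052 in COL1 over STIFF HR-negative cells. The share of cells with a Mki67 or Top2a UMI was 2.82% in SOFT.

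At the coarser clustering, the HR-negative share was 17.8% in COL1, 12.6% in STIFF, 15.3% in MATR and 18.4% in SOFT. The immune-like share was 14.3% in COL1.

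With each pool clustered alone, the basal-like share was 6.73% in STIFF. The HR-negative share was 20.03% in COL1 and 27.3% in STIFF.

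Without thinning, the share of basal-like cells with both keratin groups was 93.0% in COL1, 98.4% in STIFF, 97.2% in MATR and 93.5% in SOFT. The share of cells with a Mki67 or Top2a UMI was 9.66% in COL1, 11.4% in STIFF, 5.79% in MATR and 10.8% in SOFT.

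With 2 UMIs of each keratin group, 38.3% of basal-like cells had both in COL1, 41.1% in STIFF, 33.3% in MATR and 38.7% in SOFT.

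Over basal-like cells only, the AP-1 list was at 0.60 in COL1 over MATR, 0.68 in STIFF over SOFT, 0.054 in COL1 over STIFF and -0.011 in MATR over SOFT. Mmp13 and Il33 were at -0.045 and 0.16 in COL1 over MATR. Defb1, Pf4, Cxcl14, Gatm and F13a1 were at -0.22, 0.086, 0.087, 0.21 and 0.58 in STIFF over SOFT. Cck, Rarres2 and F13a1 were at -0.089, -0.32 and -0.53 in COL1 over STIFF. Pf4, Ccl3, Apoc2 and Tgfbi were at 0.25, 0.048, 0.31 and 0.16 in MATR over SOFT. G2/M phase, Wnt pathway, basement membrane, epithelial-mesenchymal and interstitial matrix genes were at -0.63, -0.048, -0.049, -0.037 and -0.10 in COL1 over MATR. G2/M phase and p53 target genes were at -0.37 and -0.18 in STIFF over SOFT. P53 target genes were at 0.013 in COL1 over STIFF. G2/M phase genes were at 0.082 in MATR over SOFT.

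Over luminal-like cells only, the AP-1 list was at 0.24 in STIFF over SOFT and 0.12 in MATR over SOFT. Fabp4 and Cck were at -0.014 and -0.11 in COL1 over MATR. Cd52 was at 0.051 in STIFF over SOFT. Cck was at -0.45 in COL1 over STIFF. Mgp, Ccl6, Il1b, Ccl3 and Tgfbi were at -0.092, 0.042, 0.086, 0.019 and 0.025 in MATR over SOFT. Wnt pathway and basement membrane genes were at -0.13 and -0.021 in COL1 over MATR. S phase genes were at 0.030 in MATR over SOFT.

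With tags ignored, the AP-1 list was at 0.18 in kept barcodes of the COL1 and STIFF pool over the other. Pf4, Defb14, Gpx3 and Prom2 were at -0.41, 0.83, 1.21 and 0.18 with whole pools compared.

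Without unnamed clusters, the AP-1 list over all singlets was at 0.25 in STIFF over SOFT, 0.017 in COL1 over STIFF and 0.18 in MATR over SOFT.

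Without the highest doublet scores, the basal-like share was 6.01% in STIFF. The HR-positive share was 47.9% in STIFF, 56.8% in MATR and 56.1% in SOFT. Luminal keratin genes were at 0.067 in COL1 over MATR basal-like cells. Luminal marker genes were at 0.35 in COL1 over MATR immune-like cells.

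With cells thinned, the AP-1 list over all singlets was at 0.28 in STIFF over SOFT and 0.16 in MATR over SOFT. P53 target genes were at -0.027 in STIFF over SOFT fibroblast-like cells. NF-kB and inflammatory genes were at -0.085 in MATR over SOFT fibroblast-like cells.

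With cells weighted equally, the AP-1 list over all singlets was at 0.33 in COL1 over MATR, 0.27 in STIFF over SOFT and 0.15 in MATR over SOFT.

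With members of at least 20 CPM, the AP-1 list over all singlets was at 0.40 in STIFF over SOFT and 0.25 in MATR over SOFT. Wnt pathway genes were at -0.29 in COL1 over MATR singlets. NF-kB and inflammatory genes were at -0.21 in MATR over SOFT fibroblast-like cells.

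With scaling by the trimmed mean of M-values, the AP-1 list over all singlets was at 0.21 in COL1 over MATR, 0.25 in STIFF over SOFT and 0.25 in MATR over SOFT.

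With median-of-ratios scaling, the AP-1 list over all singlets had the same rounded values.

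With tags exchanged in the COL1 and STIFF pool, the AP-1 list over all singlets was at 0.21 in COL1 over MATR, 0.33 in STIFF over SOFT and 0.022 in COL1 over STIFF. The basal-like, HR-positive, HR-negative and fibroblast-like shares were 7.87%, 44.0%, 7.67% and 6.16% in COL1 and 14.7%, 33.7%, 11.3% and 10.5% in STIFF. 0 of the 22 genes named over all singlets in COL1 over STIFF kept their direction. Defb14 and Gpx3 were at 0.50 and 0.91 in COL1 over MATR singlets. Adm, Gpx3 and Krt19 were at -0.73, 1.01 and 0.088 in COL1 over MATR basal-like cells. Defb14 was at 0.58 in COL1 over MATR HR-positive cells. F13a1 was at 0.14 in STIFF over SOFT singlets. Pf4, Mmp13, Cck, Fabp4, Rarres2, F13a1, Aebp1, Cryab, Ndrg1, Mfap5, Klk1b27, Gpx3, Defb14, Ptn, Tnxb, Klk1, Smim38, Acot1, Cdo1 and Hist1h4i were at -1.78, -1.47, -1.31, -1.28, -1.20, -1.12, -1.05, -1.02, -1.004, -0.998, 3.11, 2.01, 1.77, 1.66, 1.37, 1.29, 1.20, 0.91, 0.90 and 0.86 in COL1 over STIFF singlets. Gsta4 and Cited1 were at 0.81 and 0.81 in COL1 over STIFF singlets. Adm, Egln3, Espn, Nox4, Fxyd4, Vegfa, Sprr2f, Klk1b27, Gpx3, Fn1, Ptn and Krt4 were at -2.03, -1.45, -1.37, -1.35, -1.28, -1.24, 3.68, 2.92, 2.57, 1.91, 1.91 and 1.45 in COL1 over STIFF basal-like cells. Ndrg1, Ero1l, Gja1, Mt2, Ffar4, Mt1, Klk1b27, Gpx3, Ptn, Defb14, Tnxb and Klk1 were at -1.63, -1.27, -1.25, -1.16, -1.16, -1.05, 3.95, 2.17, 1.86, 1.81, 1.54 and 1.52 in COL1 over STIFF HR-positive cells. Hrct1, Sparcl1, Ddit4, Ifi27l2a, Clca3a2, Cyp1b1, Bglap3, Areg, Gpx3, Tagln, Pcp4 and Cck were at -0.97, -0.93, -0.84, -0.73, -0.66, -0.66, 1.12, 1.09, 1.07, 1.05, 0.92 and 0.88 in COL1 over STIFF HR-negative cells. Milk protein genes were at 0.21 in COL1 over MATR HR-negative cells. Luminal keratin, HR-positive marker and milk protein genes were at 0.18, 0.38 and -0.032 in COL1 over MATR basal-like cells. Hypoxia and immediate early genes were at -0.0053 and -0.12 in COL1 over MATR fibroblast-like cells. Interferon response and luminal marker genes were at 0.14 and 0.62 in COL1 over MATR immune-like cells. TGF-beta target genes were at 0.0011 in STIFF over SOFT HR-positive cells. S phase, heat shock and p53 target genes were at -0.12, -0.0058 and -0.0031 in STIFF over SOFT singlets. AP-1, cholesterol synthesis, hypoxia, basal marker, milk protein and immediate early genes were at 0.18, -0.24, -0.13, 0.62, 0.24 and -0.20 in COL1 over STIFF HR-negative cells. TGF-beta target, YAP/TEAD target, cholesterol synthesis and integrin and focal adhesion genes were at -0.12, -0.12, -0.13 and -0.11 in COL1 over STIFF HR-positive cells. G2/M phase, S phase, heat shock and p53 target genes were at 0.20, 0.20, 0.16 and 0.16 in COL1 over STIFF singlets. Basal keratin, luminal keratin, cholesterol synthesis, hypoxia and HR-positive marker genes were at 0.44, 0.77, 0.28, -0.39 and 0.81 in COL1 over STIFF basal-like cells. G2/M phase, NF-kB and inflammatory, S phase, hypoxia, interferon response, luminal marker, matrix remodelling and p53 target genes were at 0.42, 0.50, 0.50, -0.37, 0.60, 0.85, -0.35 and 0.42 in COL1 over STIFF fibroblast-like cells. AP-1, luminal marker and immediate early genes were at -0.16, 1.02 and -0.32 in COL1 over STIFF immune-like cells.

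With tags exchanged in the MATR and SOFT pool, the AP-1 list over all singlets was at 0.33 in COL1 over MATR, 0.21 in STIFF over SOFT and -0.22 in MATR over SOFT. The basal-like, HR-negative and immune-like shares were 3.97%, 11.3% and 13.2% in MATR and 7.72%, 13.3% and 6.56% in SOFT. Of genes named over all singlets, 11 of 23 in COL1 over MATR and 0 of 24 in MATR over SOFT kept their direction. Pf4, Ccl2, Ccl3, Ccl6, Krt78, Krt4, Defb14, Krt79, Gpx3, Mlph, Prom2 and Pdzk1ip1 were at -0.34, -0.019, -0.0069, -1.002, 0.20, 0.10, 0.69, 0.067, 0.71, 0.10, 0.38 and 0.24 in COL1 over MATR singlets. Reg3b, Calcb, Lcn2, Cp, Krt78, Krt79, Defb14 and Krt4 were at -0.19, -0.28, -0.61, -0.17, 0.46, 0.063, 1.01 and 0.25 in COL1 over MATR HR-positive cells. Cbr2 was at 0.17 in COL1 over MATR HR-negative cells. Pf4, Cxcl14, Gatm and Cd52 were at 0.12, 0.33, 0.0074 and 0.43 in STIFF over SOFT singlets. Foxq1 was at 0.38 in STIFF over SOFT HR-negative cells. Defb14, Gpx3, Krt78, Krt4, Krt79, Sprr2f, Prom2, Mgp, F3, Cxcl15, Pdzk1ip1, Mlph, Ccl6, Pf4, Cxcl2, Il1b, Ccl2, Srgn, S100a4 and Lyz2 were at -1.97, -1.81, -1.80, -1.51, -1.32, -1.28, -1.26, -1.18, -1.18, -1.17, -1.09, -1.06, 2.44, 2.24, 2.09, 1.82, 1.73, 1.65, 1.63 and 1.59 in MATR over SOFT singlets. Ccl3, Cxcl14, Apoc2 and Tgfbi were at 1.55, 1.52, 1.503 and 1.43 in MATR over SOFT singlets. Defb14, Gpx3, Krt78, Krt4, Krt79, F3, Reg3b, Lcn2, Dusp2, Cald1, Calcb and Clu were at -2.25, -1.91, -1.74, -1.40, -1.30, -1.24, 2.26, 1.84, 1.83, 1.79, 1.72 and 1.49 in MATR over SOFT HR-positive cells. Cbr2, Pdzk1ip1, Atp6v1b1, Egr2, Btg2, Klf6, Foxq1, Igfbp7, Hmox1, Timp3, Ddit4 and Tcim were at -1.48, -1.25, -0.95, -0.94, -0.92, -0.91, 1.495, 1.43, 1.26, 1.10, 0.89 and 0.81 in MATR over SOFT HR-negative cells. Milk protein genes were at 0.37 in COL1 over MATR HR-negative cells. Contractile apparatus, integrin and focal adhesion and matrix remodelling genes were at -0.29, -0.082 and -0.11 in COL1 over MATR HR-positive cells. Luminal marker genes were at 0.38 in COL1 over MATR immune-like cells. Integrin and focal adhesion and interferon response genes were at 0.068 and 0.19 in STIFF over SOFT HR-positive cells. AP-1, Wnt pathway, hypoxia, milk protein and immediate early genes were at -0.41, 0.28, 0.17, -0.62 and -0.53 in MATR over SOFT HR-negative cells. TGF-beta target, YAP/TEAD target, contractile apparatus, epithelial-mesenchymal, hypoxia, integrin and focal adhesion, interferon response, matrix remodelling and immediate early genes were at 0.32, 0.22, 0.36, 0.33, -0.25, 0.24, 0.60, 0.37 and -0.17 in MATR over SOFT HR-positive cells. G2/M phase and S phase genes were at 0.15 and 0.14 in MATR over SOFT singlets. AP-1, luminal keratin, contractile apparatus, interstitial matrix, luminal marker, milk protein and immediate early genes were at -0.28, -1.02, -0.73, -0.65, -0.95, -0.46 and 0.16 in MATR over SOFT immune-like cells.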

Other observations

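Fibroblast-like cells were not alike in inflammatory and cell cycle genes across conditions, in lists chosen after their values were seen. Apart from the test of surface antigen genes, the tests in this part were chosen only after the result was seen. NF-kB and inflammatory genes were at 0.46 (4 of 13 higher, 2 lower, percentile 100) in COL1 over MATR, led by the chemokine Cxcl2 at 1.79, with Cxcl10 at -2.51 lowest. In COL1 over STIFF they were at -0.50 (1 of 14 higher, 6 lower, percentile 0), with the acute phase gene Saa3 at -2.55 and the chemokine Cxcl5 at -2.34 lowest. Under the relative tag rule they were at 1.10 (9 of 12 higher, 1 lower, percentile 100) in STIFF over SOFT, led by Cxcl5 at 2.17 and Saa3 at 1.62, and at 0.27 (4 of 12 higher, 5 lower, percentile 99.86) in MATR over SOFT, where members went both ways, from Cxcl10 at 3.66 to Saa3 at -2.18. The last median turned to -0.21 when only members of at least 20 CPM were used, and to -0.08 with cells thinned. G2/M phase genes were at 0.74 (11 of 18 higher, 0 lower, percentile 100) in STIFF over SOFT, with Mki67 at 1.36 and Top2a at 1.14, and at 0.57 (8 of 18 higher, 0 lower, percentile 100) in MATR over SOFT. The p53 targets were at -0.42 (0 of 11 higher, 5 lower, percentile 0) in COL1 over STIFF and at 0.40 (2 of 11 higher, 0 lower, percentile 100) in STIFF over SOFT, with the ubiquitin ligase gene Mdm2 at -1.54 in the first. The STIFF over SOFT median turned to -0.03 with cells thinned. Luminal markers, which fibroblasts should lack, were at -0.85 (0 of 7 higher, 5 lower, percentile 0) in COL1 over STIFF and 0.50 (3 of 7 higher, 0 lower, percentile 100) in STIFF over SOFT fibroblast-like cells.

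The share of barcodes without a called tag differed between classes in both pools. Lower depth of the untagged classes was argued against, since among barcodes of 10000 to 20000 UMIs the HR-negative share without a tag exceeded the HR-positive share by 57.3 points or more in either pool. Less of the antigen that the hashtag antibodies bind is a candidate explanation, because H2-K1, H2-D1 and B2m were higher in tagged than in untagged HR-negative barcodes of that depth, by a mean log2 ratio of 0.41 in the COL1 and STIFF pool and 0.69 in the other. In the same barcodes HR-positive markers were also higher in tagged ones, at 0.21 and 0.49, so mixed cells stay open, and fibroblast-like cells held H2-K1 at 943 CPM, near the 1027 CPM of HR-negative cells, with 44.8% and 50% untagged. Immune-like cells held H2-K1 at 1381 CPM, below the 2140 CPM of HR-positive cells, yet 3.28% and 0% of them were untagged, against 21.9% and 19.5% of HR-positive barcodes, so the level of H2-K1 alone did not order the classes. The leukocyte antigen gene Ptprc was at 146 CPM in immune-like cells and at most 2.92 CPM elsewhere. No explanation by the culture condition was tested for this pattern.

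Hypoxia and glycolysis genes were lower in STIFF than in COL1 and SOFT in basal-like, fibroblast-like and HR-negative cells, and did not stand apart in HR-positive and immune-like cells. In fibroblast-like cells MATR was lower too, at 0.35 (percentile 100) in COL1 over MATR and -0.40 (percentile 0) in MATR over SOFT. In HR-negative cells COL1 over MATR was at -0.15 (percentile 0.185) and MATR over SOFT at -0.17 (percentile 0.005). The pattern was thus not particular to STIFF in either class. For the COL1 over STIFF part a difference between channels is argued against, as both cultures shared 1 channel and the lower of the basal-like and fibroblast-like medians was 0.37. For the STIFF over SOFT part, at -0.47 in HR-negative cells, channel and condition cannot be told apart. Tag calling is argued against as the whole cause, since under the relative tag rule the smallest of 3 medians in basal-like and HR-negative cells was still 0.21 in size and outside the random range. A response of cells to the culture condition may underlie the basal-like COL1 over STIFF median of 0.39, but with 1 culture per condition it cannot be told apart from a difference between single cultures.

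The AP-1 list was higher in the COL1 and STIFF pool than in the MATR and SOFT pool. Over all kept barcodes with tags ignored its median was 0.18, which channel and condition would both give, so they cannot be told apart. Within 1 channel the all-singlet median was -0.022 in COL1 over STIFF and 0.22 in MATR over SOFT, the last at 0.13 under the margin rule. In HR-positive cells MATR over SOFT was at 0.01 (percentile 62.21), against 0.32 (percentile 100) in COL1 over MATR and 0.29 (percentile 99.98) in STIFF over SOFT, while in HR-negative cells it was at 0.41 (percentile 100). The culture condition may raise the list, but 1 culture per condition leaves this open.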
